A study of Rattus norvegicus with 12 samples.

How the data were processed

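Esophageal tissue of rats after esophagoduodenostomy (BE) and of untreated rats (NC) was studied in 12 libraries, 3 input and 3 m6A-immunoprecipitated (IP) libraries per state. Groups and replicate numbers were taken from the labels. Per the labels' protocols, total RNA was immunoprecipitated with an m6A kit, and IP and input libraries were made with a whole-RNA library kit. Per the submitters' processing notes, reads were trimmed with cutadapt 1.9.3 and aligned with HISAT2 2.0.4. The genome build, the gene annotation, the counting tool and its use of strand, and the version and control of the peak caller are not given in the sources used here.

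Gene expression came from 1 table of the input libraries, with Ensembl gene identifiers and symbols. The authors deposited counts of reads per gene there, as whole numbers, and these 6 columns were used. Another 6 per-sample columns, headed as normalized values, were not used. Each IP library had a peak list of its own, whose peak names carry the name of the MACS caller. Per the file headers, it gave position, length, a score of -10 times log10 of p, a fold enrichment and an FDR in percent for each peak. The lowest score was at or just above 50 in every list. The authors' fold enrichment served to rank and filter peaks within a list. Otherwise it is given only for single peaks and as a median per list. The deposited percent FDR was not used, since 23.5% to 39.3% of peaks in a list carried the value 100. Coordinates are printed counting the first base as 1, on the assumption that the lists count from 0 as BED files do.

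The table held 17450 genes. Of these, 32 had no symbol, and 210 symbols were shared by several genes, for which the gene with the highest total count was taken. Total counts per library ran from 11213531 to 17471748. The 20 most abundant genes took 14.6% to 15.8% of counts in BE and 24.4% to 25.6% in NC, and mitochondrial genes 4.01% to 4.77% in BE and 7.26% to 8.80% in NC. Pearson correlations of log2 CPM were 0.921 to 0.960 within BE, 0.952 to 0.962 within NC and 0.773 to 0.838 between the groups. Principal component 1 (69.3% of variance) separated the groups, and component 2 (13.6%) set BE replicate 1 apart. A chi-square statistic of 19.9 to 77.1 per gene between libraries of a group showed none to be a copy of another. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

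Counts were fitted with edgeR 4.0.16 in R 4.3.3: filterByExpr (a minimum of 10 counts, here 0.629 CPM, in at least 3 libraries), TMM scaling, robust quasi-likelihood fits and two-sided quasi-likelihood tests of BE against NC input without covariates. This left 13761 genes tested and 3689 not tested. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of the F statistic. Genes at 0 in a group were compared against a floor of 3 counts over the group, and genes with 1 to 3 counts by an exact interval of the ratio at 95% confidence. The 21 gene lists, fixed before the data were examined, were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists, then with an estimated correlation and with fry. Setting genes at 0 in a group to their bound left each list median as it was.

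Peaks were assigned to genes by the names in the lists, and 98.1% to 98.2% of peaks in a list named a gene of the table. The 113141 peaks of the 6 lists were merged where they overlapped by at least 1 bp. A region or gene was BE-only if all 3 BE IP libraries and no NC IP library had a peak on it, and NC-only in the reverse case. Gene counts were taken among the genes tested for expression. Gene sets were tested with camera on the input fit, fixed lists with two-sided Fisher's exact tests against all tested genes, adjusted over lists and directions. Numbers and widths of peaks were compared by two-sided exact permutation tests, whose smallest p is 0.1. Position along transcripts and sequence motifs were not analysed here. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.

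The genes named were chosen by a rule fixed before the data were examined. It took the 10 strongest rises and 10 strongest falls with a proper symbol, a change of at least 2-fold, groups that did not overlap and a mean of at least 5 CPM in the higher group. Chance alone separates 3 libraries from 3 in 10% of genes. It added up to 4 members of each list that passed and 2 that did not, every m6A machinery gene, and 8 genes per direction with group-specific m6A that changed less than 2-fold, by rank of fold enrichment, with up to 8 that changed. Further members named to complete a count of 5 or fewer were chosen after their values were seen. So were 3 added lists: hepatocyte (31 genes, 12 of them seen before listing), interferon response (25 genes, 11 seen before) and biliary and ductal epithelium (11 genes). In the added biliary list, 2 of 11 genes were over 2-fold higher in BE replicate 1 than in any other library.

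The expression test was tested on simulated counts drawn from the means, library sizes and dispersions of the 13761 genes. The changed genes were taken only from those with a mean over 5 CPM, so recovery of rarer genes was not tested. The first run, with 200 genes changed, gave 13.9% false calls, over a limit of 10% that had been set as a stop; the limit was then removed and more runs were made. Over 20 such runs the mean false share was 9.09% (5.38% to 13.9%) against a nominal 5%, and the test recovered 38.6% of genes changed 2-fold and 87.5% of those changed 4-fold. With 2000 genes changed, 10 runs gave 4.04% false calls (3.36% to 4.64%) and recovered 65.4% and 94.2%. With dispersions on a smooth trend and 200 genes changed, the false share was 4.20%. DESeq2 gave 21.8%, 6.95% and 12.9% false calls in these 3 settings. An unchanged gene set passed camera at an unadjusted p under 0.05 in 1 of 20 runs. Genes were drawn independently in these runs, so they do not test camera on correlated genes. The lists that passed in the data had estimated correlations of 0.116 to 0.390. The merging of peaks recovered all 3000 planted regions.

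Alternatives fixed beforehand were the replicate number as a block, no filter on low counts, DESeq2 1.42.0 with its own size factors, voom with library quality weights, each library left out in turn, a minimum fold enrichment of 4, a reciprocal overlap of 50%, presence in at least 2 of 3 libraries, lists of equal length, genes expressed in both groups, and those of them changed less than 2-fold. Restriction to genes changed less than 1.2-fold, equal length combined with either expression limit, Fisher's tests without each IP library, gene sets without BE IP replicate 1, and a fit without the 20 most abundant genes of each library, scaled by the remaining counts and read for the cell cycle and inflammatory lists only, were chosen after seeing the data. Every result of a model was also set against the 9 other splits of the 6 libraries into 3 and 3.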

Results

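RNA was measured in esophageal tissue from rats in 2 states. The BE group had undergone esophagoduodenostomy, an operation that joins the esophagus to the duodenum so that duodenal contents reach the esophageal lining, and serves as a rat model of Barrett's esophagus, in which squamous epithelium is replaced by columnar epithelium. The NC group was untreated. Each of the 6 tissue samples gave an input RNA-seq library and a library immunoprecipitated with an antibody against N6-methyladenosine (m6A), a methyl mark on messenger RNA. The 12 libraries thus formed 4 groups of 3: BE input, NC input, BE IP and NC IP. Input libraries were read as gene counts, and IP libraries as lists of peaks, regions where the antibody enriched RNA. Total gene counts were 17471748, 15543460 and 16270167 in BE input replicates 1 to 3, and 11213531, 16863737 and 14686281 in NC input replicates 1 to 3. The depth of the IP libraries is unknown. Nothing in the labels says that the samples came from separate animals, so p-values measure the spread between these samples, which may be technical.

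The first comparison asked which transcripts differed between surgically refluxed and untreated esophagus. In BE tissue the fixed lists of striated muscle, smooth muscle and nerve genes fell, and those of cell cycle, inflammatory and squamous genes rose, calls that were all lost when the correlation between genes was estimated (adjusted p of 0.0611 to 0.450). Of 13761 genes tested, 2999 rose and 2996 fell in BE (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 1420 rose and 1964 fell by at least 2-fold. The common biological coefficient of variation was 0.324. Levels are given as CPM, counts scaled to library size, as mean ± SD over n = 3 libraries per group, and fold changes are log2 of BE over NC ± SE.

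Among the 10 strongest rises, Mmp10, a stromelysin that degrades matrix, stood at 153 ± 72.9 CPM in BE and 0.476 ± 0.235 in NC, a log2 fold change of 8.27 ± 0.66. Il24, a cytokine of the interleukin 10 family, rose by 7.81 ± 0.58, from 0.112 ± 0.102 to 25.3 ± 8.50 CPM. Sprr2g, a small proline-rich protein of the cornified envelope, rose by 7.63 ± 0.28, from 0.610 ± 0.282 to 120 ± 15.3 CPM. The chemokine Cxcl6 and the vitamin D 24-hydroxylase Cyp24a1 had no counts in NC. Against a floor of 3 counts over the NC group they were at least 85.6-fold and at least 64.7-fold higher in BE. Nppb, Irx1, Hal, Slc5a8 and Chst5 completed the list with 1 NC count each. Their BE to NC ratios were 517 for Nppb (95% counting interval 92.5 to 20450), 345 for Irx1 (61.7 to 13662), 347 for Hal (62.0 to 13746), 285 for Slc5a8 (50.9 to 11295) and 267 for Chst5 (47.7 to 10591). Hal, which encodes histidine ammonia-lyase, reached 21.7 CPM in BE replicate 1 and 1.49 and 2.76 in BE replicates 2 and 3, and its adjusted p became 0.0863 without NC replicate 3.

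Among the 10 strongest falls, Actc1 and Actn3 belong to the striated muscle list. Actc1, cardiac alpha-actin, fell by 7.12 on the log2 scale (SE 0.43), from 3278 ± 789 to 23.5 ± 9.19 CPM. Actn3, the fast-fiber alpha-actinin, fell by 6.89 (SE 0.90), from 742 ± 139 to 6.23 ± 4.94 CPM. Sbk2, an SH3-binding kinase family member, stood at 84.7 ± 36.4 CPM in NC and 0.0894 ± 0.109 in BE. Wfikkn2, which encodes a protease inhibitor that binds myostatin, had no counts in BE and was at least 137-fold lower. Mylk4, Me3, Cadm2, Dnah5, Ccna1 and Sbk3 made up the rest, with BE means between 0.0176 and 0.222 CPM. The calls of Sbk2, Sbk3 and Mylk4 ended when libraries were weighted by quality, at adjusted p = 0.112, 0.0769 and 0.288 with voom.

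In the list of striated muscle genes, 42 of 46 tested members fell, 1 rose and 3 did not pass; adjusted over the list alone, 43 fell and 1 rose. The esophageal muscle coat of the rat is striated. The median log2 fold change was -4.40, and the list fell against the other genes (camera, adjusted p = 1.9e-63), a call that was lost at adjusted p = 0.0611 with an estimated correlation. Atp2a1, the calcium pump of fast fibers, fell from 4824 ± 200 to 123 ± 30.5 CPM (log2 fold change -5.29 ± 0.20). Myh4, a fast myosin heavy chain, went from 856 ± 590 to 7.26 ± 3.04 CPM, a call that ended when libraries were weighted by quality (adjusted p = 0.113 with voom). Tpm3, a tropomyosin that is also made outside muscle, rose by 1.30. Myh2 stood at 173 ± 65.8 CPM in BE and 788 ± 693 in NC without passing, though it passed with DESeq2 (adjusted p = 0.0148). Myosin and actin genes are close paralogs, and how shared reads were assigned is not given in the sources used here.

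Smooth muscle genes fell as well: 23 of 29 fell, 1 rose and 5 did not pass, with 24 falls and 1 rise adjusted over the list alone. The median was -2.75 (camera, adjusted p = 2.0e-22; adjusted p = 0.179 with an estimated correlation). Lmod1, an actin filament nucleator, fell from 128 ± 15.1 to 3.79 ± 0.762 CPM, and Tpm1 from 2865 ± 290 to 223 ± 33.7 CPM. Chrm2, the M2 muscarinic receptor, had no counts in BE and was at least 72.9-fold lower. Notch3, the receptor typical of vessel-wall cells, rose by 0.75. Rgs5, a pericyte gene, was alike in both groups at 56.9 ± 11.7 and 56.9 ± 1.74 CPM.

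Of 19 tested genes of nerve, Schwann cells and enteric glia, 8 fell, none rose and 11 did not pass; adjusted over the list alone, 8 fell and 1 rose. The median was -2.12 (camera, adjusted p = 0.0137; adjusted p = 0.450 with an estimated correlation). Nos1, the nitric oxide synthase named neuronal, fell from 70.7 ± 20.8 to 1.87 ± 1.18 CPM, and S100b, a glial calcium-binding protein, from 26.6 ± 11.4 to 1.35 ± 1.39. Which cells of the tissue these transcripts came from was not tested. The call of S100b ended with the replicate number as a block (adjusted p = 0.0713) and in 4 other fits. The list's call also ended with DESeq2 (adjusted p = 0.0614) and without BE replicate 1 (0.0931).

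Cell cycle genes rose almost throughout. Of 37 tested members, 36 rose, and the same number did adjusted over the list alone; the exception was E2f1 at 4.78 ± 0.579 and 2.52 ± 2.06 CPM, whose log2 fold change of 0.94 became 1.80 and passed without NC replicate 1 (adjusted p = 0.0434), and passed with voom (1.48, adjusted p = 0.0444). The median log2 fold change was 1.98 (camera, adjusted p = 8.0e-22; adjusted p = 0.179 with an estimated correlation). Rrm2, a subunit of the enzyme that makes deoxyribonucleotides, rose from 5.36 ± 1.47 to 82.1 ± 27.6 CPM. Mybl2, a transcription factor of the cell cycle, rose from 4.07 ± 0.850 to 47.6 ± 10.6. The replication helicase subunits Mcm3 and Mcm6 each rose by 2.95.

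Inflammatory mediators rose too: 22 of 31 passed, none fell and 9 did not pass, with the same counts adjusted over the list alone. The median was 2.60 (camera, adjusted p = 5.6e-10; adjusted p = 0.179 with an estimated correlation). Besides Cxcl6, the neutrophil chemokine Cxcl2 rose by 5.55 ± 0.90, while Cxcl3 and the inducible nitric oxide synthase Nos2 had no counts in NC and were at least 36.8-fold and at least 45.9-fold higher. Nos2 makes nitric oxide in activated cells, and stood at 3.54 ± 0.755 CPM in BE. The alarmin Il33 (144 ± 24.7 and 136 ± 9.36 CPM) and the adhesion molecule Vcam1 (26.9 ± 6.72 and 31.3 ± 3.00) did not pass. BE replicate 1 differed from its group in interferon-response genes. A list of 25 such genes, drawn up after the libraries had been examined, summed to 4774 CPM there, against 289 to 539 CPM in the other 5 libraries.

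Squamous epithelium and cornification genes rose in majority: 34 of 47 rose, 3 fell and 10 did not pass, and adjusted over the list alone 34 rose and 4 fell. The median was 0.82 (camera, adjusted p = 6.4e-12; adjusted p = 0.312 with an estimated correlation). Krt16 and Krt17, keratins of stressed and wounded epidermis, rose by 7.35 ± 0.35 and 7.31 ± 0.25. Krt17 went from 4.46 ± 1.35 to 703 ± 64.5 CPM. The basal keratin Krt14 rose from 292 ± 27.0 to 3482 ± 914 CPM. Krt80, Krt78 and Ecm1 fell by 1.18, 0.81 and 0.63 on the log2 scale. Periplakin (Ppl, 1551 ± 290 and 2047 ± 270 CPM) and Calml3 (718 ± 107 and 799 ± 108 CPM) did not pass. Ppl passed downwards with DESeq2, with voom and without BE replicate 1 or NC replicate 1, at adjusted p of 0.0118 to 0.0347. Keratins and small proline-rich proteins are multigene families whose shared reads leave single members uncertain.

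Columnar markers did not move together. Among 15 tested members of the intestinal columnar list, Rbp2, Epcam and Slc5a1 rose by 1.86, 1.03 and 0.61. Of 5 that fell, Lgr5, Anpep, Slc6a19 and Slc15a1 did so by 2.79, 1.23, 1.10 and 0.55 on the log2 scale, and 7 did not pass; the counts were the same adjusted over the list alone. The list as a whole did not pass (median 0.61; camera, adjusted p = 0.785), and its median turned to -0.80 without BE replicate 1, -0.53 with voom and -0.28 with the replicate number as a block. Lgr5, a stem cell receptor, lay near the threshold (adjusted p = 0.0492) and lost its call in 5 of the 10 other fits; that of Anpep, an aminopeptidase, ended in 7. Apob and Pigr had the highest means among members that did not pass. Pigr, the receptor that carries immunoglobulins across epithelium, stood at 140 CPM in BE replicate 1 and at 0.287 and 0.113 CPM in replicates 2 and 3. Without replicate 1 its log2 fold change turned from 4.18 to -3.62 (adjusted p = 0.0114), and it was also negative with the replicate number as a block (-0.28) and with voom (-1.45). Cdx1, Cdx2, Tff1, Tff2, Tff3 and Gkn1 were not analysed here.

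Of 4 tested genes of the goblet, secretory and enteroendocrine list, Reg3b, an antimicrobial lectin, was at least 14.3-fold higher in BE, and Dclk1, a kinase of tuft cells and neurons, fell by 2.68. Creb3l1 and Galnt12 did not pass (list median 0.05; camera, adjusted p = 0.785, test direction down). Without single libraries that median ran from -0.26 (without NC replicate 1) to 0.49 (without NC replicate 3). It was -2.20 over 17 genes without the filter on low counts. Of 3 tested gastric genes, Capn8 fell by 1.94, a call that ended without NC replicate 3 at adjusted p = 0.0600, and Ctse and Krt19 did not pass (median -1.60; camera, adjusted p = 0.827). The gastric median ran from -2.33 without BE replicate 1 to -0.29 and 0.11 without NC replicates 2 and 1. Without the filter on low counts it was 1.71 over 19 genes. Both lists gave the same counts adjusted over the list alone. Krt18 and Krt8, keratins of simple epithelium that were too rare elsewhere to be tested and were named after their values were seen, stood at 33.5 and 9.33 CPM in BE replicate 1 and at or under 0.631 CPM in the other 5 libraries. Of 16 tested Barrett-associated transcription factors and signals, 9 rose, Ptch1 fell by 0.77 and 6 did not pass, with the same counts adjusted over the list alone (median 0.53; camera, adjusted p = 0.112). The squamous stem cell factor Tp63 rose from 220 ± 14.9 to 677 ± 55.2 CPM, Nfkb1 from 74.7 ± 2.48 to 154 ± 19.5 and Pitx1 from 61.2 ± 8.26 to 120 ± 10.9. The list shares Tp63, Sox2, Pax9 and Klf5 with the squamous list, so its rises do not stand for columnar factors alone. Atoh1, Shh and Ihh, like Cdx1 and Cdx2, were not analysed here.

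**Figure D1:**
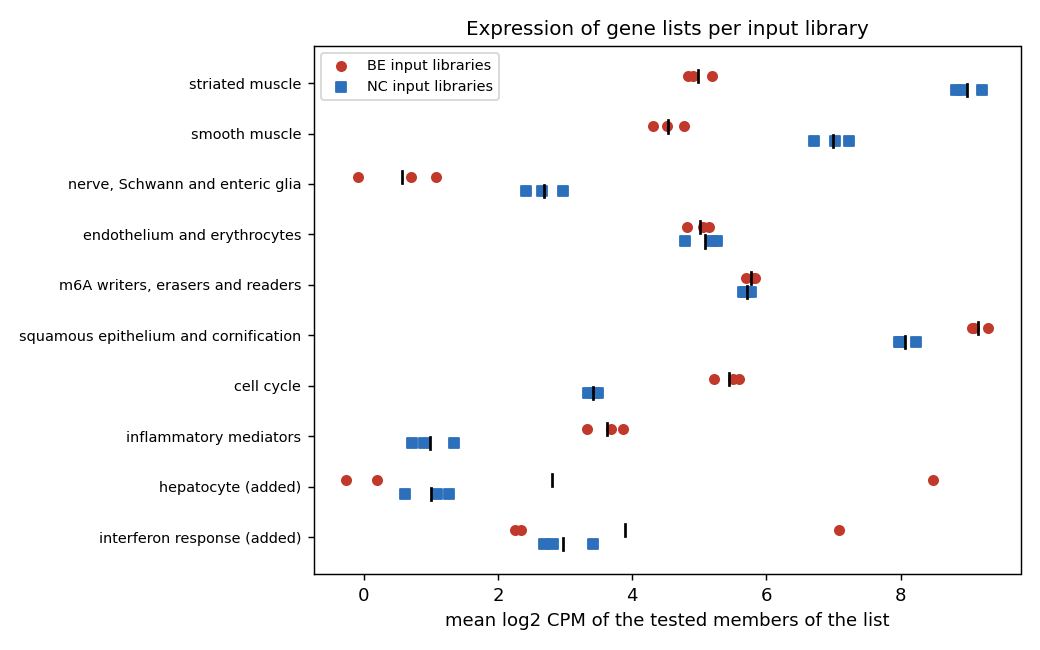
Mean log2 CPM of the tested members of each gene list (horizontal axis, log2 scale) in the 6 input libraries; red circles are BE libraries, blue squares NC libraries, and the black ticks group means. The striated muscle scores of the 3 BE libraries run from 4.83 to 5.18 and those of the 3 NC libraries from 8.83 to 9.21, while the cell cycle scores run from 5.23 to 5.59 in BE and from 3.34 to 3.49 in NC.

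BE replicate 1 also carried transcripts typical of hepatocytes, which moved with the intestinal and bile acid lists. Summed over 31 hepatocyte genes, a list drawn up after the libraries had been examined, it held 14935 CPM, against 72.4 and 94.2 CPM in BE replicates 2 and 3 and 150 to 180 CPM in the NC libraries. Albumin (Alb) stood at 3068 CPM there and between 3.21 and 6.31 CPM elsewhere. All 31 genes were over 2-fold above each of the other 5 libraries, with a median of 190-fold. Apob, which belongs to the intestinal list as well, stood at 1388 CPM in BE replicate 1 and between 1.95 and 5.93 CPM in the other libraries. The bile salt export pump Abcb11, named after its values were seen, was at 50.4 CPM in it and 3.04 CPM in BE replicate 2. Among 6 tested bile acid genes, Abcc3 rose by 0.49 (a call that ended in 4 other fits), Nr0b2, with no counts in BE, was at least 27.6-fold lower, and 4 did not pass, with the same counts adjusted over the list alone (median 0.39, or 0.19 without BE replicate 1, mean -0.25; camera, adjusted p = 0.827). The bile acid median was 5.55 over 19 genes without the filter on low counts. Without BE replicate 1, 6154 genes passed, and 5512 of the 5995 calls were among them.

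**Figure D2:**
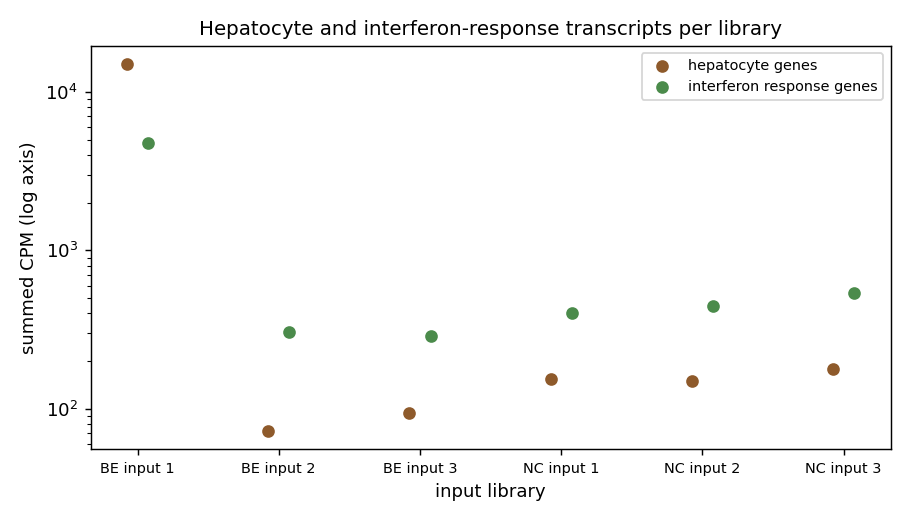
Summed CPM (logarithmic axis) of the hepatocyte and interferon-response gene lists in each of the 6 input libraries. BE replicate 1 stands at 14935 CPM for the hepatocyte list and 4774 CPM for the interferon list. The biliary and ductal list, which is not drawn, ran from 200 to 356 CPM over all 6.

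The extracellular matrix list moved both ways: 11 of 38 rose, 16 fell and 11 did not pass (13 and 19 adjusted over the list alone). Its median was -0.52, its mean 0.40 and the test direction down (camera, adjusted p = 0.827). The matrix metalloproteinases Mmp3, Mmp9 and Mmp13 rose by 7.38, 6.72 and 5.82, and Col12a1, a fibril-associated collagen, from 131 ± 16.8 to 1456 ± 398 CPM. Col1a1 (413 ± 84.5 and 637 ± 208 CPM) and Postn (291 ± 82.6 and 269 ± 97.1 CPM) did not pass, though Col1a1 passed downwards with DESeq2 (adjusted p = 0.00689) and without NC replicate 1 (0.0499). The call of Mmp3 ended when libraries were weighted by quality (adjusted p = 0.0942 with voom).

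Leukocyte lists did not pass as wholes. Of 25 macrophage and neutrophil genes, 6 rose, Trem2, Csf1r and Cd163 fell by 2.91, 1.04 and 0.78, and 16 did not pass (5 and 3 adjusted over the list alone; median 0.42; camera, adjusted p = 0.592). That median ran from -0.18 without BE replicate 1 to 0.67 without NC replicate 3. The neutrophil calprotectin genes S100a8 and S100a9 rose by 6.28 ± 1.11 and 5.37 ± 1.22, calls that ended at adjusted p = 0.0835 and 0.156 with the replicate number as a block and in 3 and 5 other fits. Of 21 lymphoid and mast cell genes, Foxp3 and Sdc1 rose by 2.50 and 1.05, Tnfrsf17, Cpa3 and Cd4 fell, and 16 did not pass, with the same counts adjusted over the list alone (median 0.01, mean -0.05, test direction up; camera, adjusted p = 0.785). The lymphoid median ran from -0.20 without NC replicate 1 to 0.45 without NC replicate 3. Sdc1, a plasma cell marker, is also abundant in squamous epithelium. Tnfrsf17, a receptor of plasma cells, had 1 count in BE, and its NC to BE ratio was 135 (95% counting interval 23.6 to 5371). The call of Foxp3, the factor of regulatory T cells, ended with the replicate number as a block (adjusted p = 0.0559) and in 3 other fits.

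Among 28 tested m6A writers, erasers and readers, 6 rose, 2 fell and 20 did not pass; adjusted over the list alone, 6 rose and 1 fell (median 0.13, or 0.06 and 0.04 without BE replicates 2 and 3; camera, adjusted p = 0.592). The writer subunits did not pass: Mettl3 stood at 19.2 ± 2.50 and 21.5 ± 3.31 CPM in BE and NC, Mettl14 at 49.3 ± 8.30 and 42.9 ± 3.87, and Wtap at 57.4 ± 3.08 and 49.9 ± 2.42. The demethylase Fto fell by 0.94 (SE 0.17, adjusted p = 0.00123), from 72.5 ± 13.9 to 37.9 ± 4.32 CPM. Alkbh5, the other demethylase, fell by 0.40 (adjusted p = 0.0438), a call that ended with the replicate number as a block (0.0796), without the expression filter (0.0681) and without any single library but BE replicate 2. Among readers and RNA-binding proteins, Snd1 rose by 1.07, Elavl1 by 0.92, Ythdf2 and Fmr1 by 0.48, and Hnrnpa2b1 and Eif3a by 0.44. The calls of Ythdf2 and Fmr1 ended without 2 and 3 of the single libraries, at adjusted p of 0.0518 to 0.0832.

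Of 26 oxidative stress and xenobiotic genes, 11 rose, Cyp1a1, Aldh3a1, Aldh1a1 and Gpx1 fell, and 11 did not pass (12 and 4 adjusted over the list alone; median 0.26, or 0.12 without BE replicate 1; camera, adjusted p = 0.154). The cystine transporter Slc7a11 rose from 48.0 ± 4.42 to 494 ± 58.2 CPM and the aldo-keto reductase Akr1b8 from 56.5 ± 10.4 to 532 ± 78.3. Cyp1a1, a target of the aryl hydrocarbon receptor, fell from 4.44 ± 0.187 to 0.265 ± 0.411 CPM, and Aldh3a1, Aldh1a1 and Gpx1 by 2.13, 1.98 and 1.42 on the log2 scale. Of 29 immediate early and heat shock genes, 10 rose, Jund, Jun and Bag3 fell by 2.23, 1.34 and 1.04, and 16 did not pass, with the same counts adjusted over the list alone (median 0.39; camera, adjusted p = 0.154). Fosl1, an AP-1 subunit, rose by 5.67 and the chaperone Dnajb1 by 2.25.

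The remaining lists cover other cell types that an esophageal piece can hold. Of 18 adipocyte genes, Pparg, Fasn and Acaca rose by 1.23, 0.84 and 0.61, Lep, Plin4, Fabp4, Cidec and Cfd fell and 10 did not pass, with the same counts adjusted over the list alone (median -0.43, or -1.29 and -1.02 without BE replicates 1 and 2; camera, adjusted p = 0.223). Plin4, a lipid droplet coat protein, fell from 93.1 ± 8.43 to 5.43 ± 0.568 CPM, and the call of Cidec ended in 6 other fits. Of 19 endothelial and erythroid genes, Plvap, Kdr and Flt1 rose by 1.66, 0.85 and 0.58, Hbb and Lyve1 fell by 1.69 and 1.18, and 14 did not pass (3 and 1 adjusted over the list alone; median -0.14, or -0.02 without BE replicate 1, -0.22 without BE replicate 2 or 3 and -0.25 without NC replicate 1; test direction up; camera, adjusted p = 0.880). The call of Hbb ended in 7 other fits. Of 8 airway and thyroid genes, Slc5a5, an iodide transporter also found in the stomach, rose at a BE to NC ratio of 71.8 (95% counting interval 24.3 to 350), Dnah5, Bpifa1, Tshr and Tppp3 fell and 3 did not pass (median -1.75; camera, adjusted p = 0.249). Without the filter on low counts the median of this list was 0.49 over 13 genes. The call of Tshr ended without NC replicate 2, at a log2 fold change of -2.34 from -2.95 (adjusted p = 0.0887). Of 5 pancreatic acinar genes, Cpa1 fell by 3.32 and 4 did not pass (median -0.62, or -0.40 and -0.95 without NC replicates 2 and 3; camera, adjusted p = 0.785). Both of these lists gave the same counts adjusted over the list alone.

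The second comparison asked how many m6A peaks each tissue carried. Each BE library had more peaks, and a smaller median peak width, than any NC library, while the number of genes with a peak overlapped between the groups. The BE lists held 20531, 19329 and 20462 peaks and the NC lists 16644, 18864 and 17311. The means were 20107 ± 675 and 17606 ± 1139 (SD, n = 3), a difference of 2501 (two-sided exact permutation test, p = 0.1, the smallest that 3 against 3 libraries allow). The median peak width was 266 ± 14.4 bp in BE and 335 ± 38.8 bp in NC (exact permutation p = 0.1). NC replicate 2, at 291 bp, lay close to BE replicate 2, at 282 bp. The median fold enrichment was 8.59 to 9.55 in the BE lists and 9.18 in NC replicate 2. It was 13.4 and 11.6 in NC replicates 1 and 3, which held the fewest and widest peaks. Whether the lists differed in sensitivity was not tested. Genes with at least 1 peak numbered 9027 ± 127 and 8799 ± 336 (exact permutation p = 0.4). Among hepatocyte genes, 15 of 31 carried a peak in BE IP replicate 1 and 0 to 2 in the other IP libraries. Intestinal list genes with a peak numbered 13 in BE IP replicate 1 and 3 to 9 elsewhere.

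The third comparison asked which regions and genes carried m6A peaks in 1 tissue only. After overlapping peaks of the 6 lists were merged into 29269 regions, 1262 held a peak in all 3 BE libraries and in no NC library (BE-only), 755 the reverse (NC-only), and 11152 in all 6. On the level of genes, 254 were BE-only, 234 NC-only and 6500 common among the 13761 genes tested for expression. Of those expressed in both groups, 212 were BE-only and 151 NC-only. Among genes expressed in both and changed less than 2-fold, 113 were BE-only and 35 NC-only. The balance between the groups turned in other settings. When each list was limited to its 16644 peaks of highest enrichment, 170 genes were BE-only and 327 NC-only, and 667 regions and 915. With that limit, 63 genes expressed in both groups and changed less than 2-fold were BE-only and 67 NC-only. With a fold enrichment of at least 4, 230 genes were BE-only and 256 NC-only, while the regions numbered 984 and 760. No p is given per region, since 3 libraries against 3 cannot go below 0.1.

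Among BE-only genes changed less than 2-fold, Myo1e, an unconventional myosin, ranked highest by the authors' fold enrichment. Its strongest peak lay on chromosome 8 from 76298058 to 76298143, with fold enrichments of 20.5 to 27.8 for the best peak in the BE lists, at 147 ± 18.6 CPM in BE and 91.5 ± 9.23 CPM in NC. Cyp2c79, Sdr39u1, Mark4, Ppfia3, Itpa, Aig1 and Nsf came next. Not all of these were unchanged in abundance. Myo1e, Mark4, Nsf and Itpa passed upwards, at log2 fold changes of 0.69, 0.84, 0.86 and 0.92, and Sdr39u1 passed downwards at -0.92. The calls of Itpa and Sdr39u1 ended in some other fits. Mark4, a kinase that phosphorylates microtubule-associated proteins, had its strongest peak on chromosome 1 from 81601789 to 81603059. Nsf, an ATPase of membrane fusion, had its strongest peak on chromosome 10 from 91773256 to 91773271. The NC-only genes changed less than 2-fold were Hoxd4, Ctdnep1, Ercc2, Cyb5r2, Chmp4b, Morn1, Cdh6 and Ctsa. Of them, Ctdnep1 passed the expression test downwards (-0.80) and Ercc2 upwards (0.85), a call that ended in some other fits. Hoxd4, a homeobox gene, carried its strongest peak on chromosome 3 from 68099689 to 68100083, at 2.32 ± 0.169 CPM in BE and 3.67 ± 0.916 in NC. Ctsa, which encodes cathepsin A, stood at 131 ± 18.6 and 116 ± 12.6 CPM and carried its strongest peak on chromosome 3 from 167489025 to 167489974. The genome build is not given in the sources used here, so exon, intron and UTR were not assigned.

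Other genes with group-specific m6A changed by at least 2-fold in abundance. The BE-only genes with the largest expression changes were Cxcl6, Fam83a, Irx1, Chst5, Sprr2g, Unc93a, Gpr15 and Cdca5, and all 8 rose. Of the corresponding NC-only genes, Wfikkn2, Sbk2, Sbk3, Chrm2, Tll2, Sox11 and Fam198a fell. Il24 was the exception, NC-only for m6A (chromosome 13 from 52707115 to 52707575) at 0.112 ± 0.102 CPM in NC and 25.3 ± 8.50 CPM in BE. Its NC level lay under the 0.629 CPM of the expression filter. Input reads of Il24 were close to absent there, so its NC-only call is uncertain. Myl3, a myosin light chain of the striated muscle list, went the other way round, with BE-only m6A (chromosome 8 from 118370093 to 118370288) at 60.5 ± 16.7 CPM in BE and 1336 ± 623 in NC. No gene of the m6A machinery had group-specific m6A.

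The fourth comparison asked whether presence of m6A and abundance went together. Genes with BE-only m6A were mostly more abundant in BE: 143 of 254 rose (56.3%), 14 fell and 97 did not pass, with a median log2 fold change of 1.19. Genes with NC-only m6A were mostly less abundant in BE: 157 of 234 fell (67.1%), 16 rose and 61 did not pass, with a median of -2.72. Of the 6500 common genes, 21.1% rose and 22.9% fell. The BE-only set passed upwards and the NC-only set downwards (camera, adjusted p = 9.4e-15 and 2.9e-21), and both calls held at adjusted p = 0.00955 and 0.0129 with an estimated correlation; the common set did not pass (0.497). The sets were chosen on the same tissues, and a peak needs its transcript to be present, so the directions are not independent evidence.

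**Figure D3:**
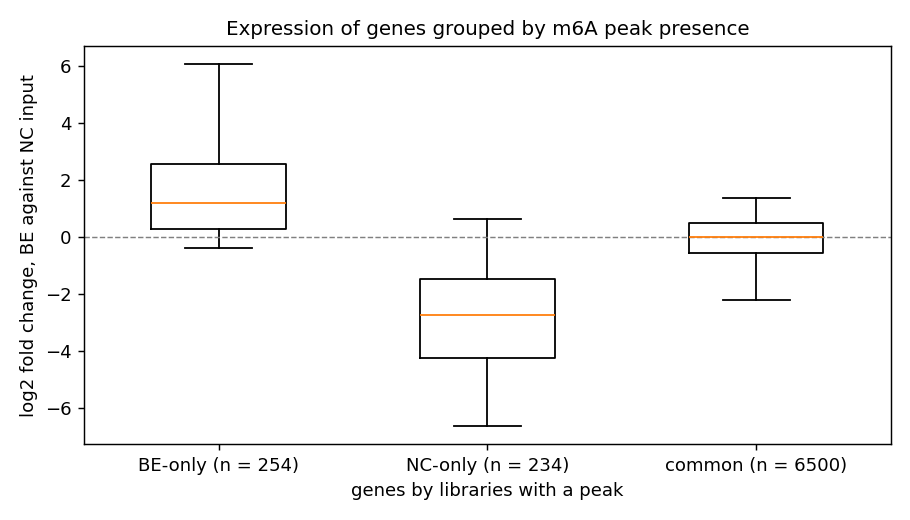
Log2 fold change of BE over NC input (vertical axis) for genes with BE-only, NC-only and common m6A; boxes span the quartiles, orange lines mark medians and whiskers reach the 5th and 95th percentiles. The median is 1.19 for the 254 BE-only genes, -2.72 for the 234 NC-only genes and -0.00 for the 6500 common genes.

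The fifth comparison asked which fixed gene groups held genes with group-specific m6A. Inflammatory mediators were over-represented among BE-only genes: Ccl2, Cxcl6, Il11, Lcn2, Lif, Osm and Sele, 7 of 31 (22.6%, against 1.80% of the other genes; Fisher's exact test, adjusted p = 5.1e-05). So were cell cycle genes, with Aurka, Cdc6, Mcm2, Mcm5 and Mybl2, 5 of 37 (13.5%; Fisher's exact test, adjusted p = 0.0116). Smooth muscle genes were over-represented among NC-only genes, with Chrm2, Kcnmb1, Myocd and Ppp1r14a, 4 of 29 (13.8%; Fisher's exact test, adjusted p = 0.0194). Among genes expressed in both groups, the inflammatory result ended at adjusted p = 0.0765, with 3 of 23 (13.0% against 1.62%; odds ratio 9.11, from 15.9), and the smooth muscle result at 0.0706, with 3 of 27 (11.1% against 1.15%; odds ratio 10.8, from 9.39). The shares stayed above those of other genes, over fewer members. The cell cycle result passed at 0.0122. That background asks only for expression at the filter level and does not match abundance. Of the cell cycle list, 36 of 37 genes rose. Mybl2, Mcm5 and Aurka stood at 47.6, 48.3 and 23.7 CPM in BE and at 4.07, 6.38 and 4.21 CPM in NC. Whether over-representation of these lists goes beyond their change in abundance was not tested. The smooth muscle result also ended without BE IP replicate 3 (0.0532) and when presence in at least 2 of 3 libraries counted (0.111).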

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

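Restriction to genes changed less than 1.2-fold, equal list length combined with an expression limit, Fisher's tests without single IP libraries, and leaving out the most abundant genes for the cell cycle and inflammatory lists (which kept both calls) were chosen after the results were seen. The counts of genes that passed, in both directions and at 2-fold, stayed within 1.5 times in all 10 other fits. With the replicate number as a block, 5223 genes passed and 3189 of them by 2-fold; the numbers did not pair the samples (correlations of same-numbered deviations -0.04, 0.006 and -0.07), and no sample correlated best with its own number. DESeq2, at 6300 and 3605, moved the median of all genes by -0.02, and without single libraries 4903 to 6154 and 2988 to 3590 passed. For causes below, unless the setting itself removes genes or libraries, the cause was not tested.

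With an estimated correlation 0 of the 6 list calls passed, at adjusted p = 0.312 (squamous), 0.0611 (striated muscle), 0.179 (smooth muscle, inflammatory mediators and cell cycle) and 0.450 (nerve); fry passed 12 lists. Those new with fry were goblet (0.0231), Barrett-associated factors (8.1e-04), oxidative stress (0.00534), airway and thyroid (8.1e-04), adipocytes (0.0172) and immediate early genes (0.0193). Barrett-associated factors also passed with voom (0.0334). The nerve list ended with DESeq2 (0.0614) and ranged from 0.00136 to 0.0931 without single libraries, the highest without BE replicate 1. Directions of lists that did not pass turned for the intestinal list with voom (0.989), the gastric list without a filter (0.758), the matrix list with the replicate block (0.928), and the endothelial list with voom (0.864) and fry (0.885). Without single libraries they turned in some cases, over ranges of 0.604 to 0.997 for the matrix list, 0.523 to 0.913 for lymphoid and mast cells, and 0.767 to 0.997 for the endothelial list. The block changed no other list call.

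Group-specific regions numbered 4454 (2993 BE-only, 1461 NC-only) with presence in at least 2 of 3 libraries, and 859 (717 and 142) in genes expressed in both groups and changed less than 2-fold. With equal list length 667 regions were BE-only and 915 NC-only, which reversed the balance; BE-only regions ranged from 1516 to 1950 without single libraries. Group-specific genes numbered 862 (481 and 381) with at least 2 of 3 and 148 (113 and 35) under 2-fold. Under 1.2-fold they numbered 46 (38 and 8). With equal length they numbered 130 (63 and 67) under 2-fold and 34 (19 and 15) under 1.2-fold. NC-only genes expressed in both groups were 151, and common genes under 1.2-fold 1786, or 1680 with equal length. A looser rule, shorter lists or fewer genes change counts by construction, but why the balance of BE-only and NC-only moved was not tested. The common set passed with fry (0.00346). Against genes expressed in both groups 1 fixed list passed: inflammatory mediators ended at 0.0765 and smooth muscle at 0.0706. Smooth muscle ended at 0.111 with at least 2 of 3 and ranged from 0.00413 to 0.0532 without single IP libraries, and NC-only intestinal genes ranged from 0.0363, without BE IP replicate 1, to 1.

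For 189 named genes, 1770 of 1887 values in other fits kept direction and side of the threshold, 87 lost and 29 gained a call. The log2 fold change of Pigr turned to -3.62 without BE replicate 1 and ranged up to 4.71 without other single libraries; it was -0.28 with the replicate block and -1.45 with voom. Peak positions were not run, and a pseudocount does not apply to counts. Genes under 0.629 CPM in more than 3 of the 6 libraries were not tested, hepatocyte genes high in BE replicate 1 alone among them.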

Other observations

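Among the tests in this part, those of a lower share of muscle, of a few abundant NC genes, of abundance at under 1.2-fold, alone and combined with list length, and the splits of the samples for expression counts, m6A regions and m6A genes were chosen only after the result was seen. The added gene lists were too.

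Of 1185 BE-only regions in tested genes, 67.6% lay in genes that had a peak in all 6 libraries, with a median log2 fold change of 0.49 over BE-only regions, of which 45.8% lay in genes that rose and 13.8% in genes that fell. Of 695 NC-only regions, 42.7% lay in such genes, with a median of -2.47 over NC-only regions, of which 8.35% lay in genes that rose and 69.9% in genes that fell; the differences were not tested. Of the 29269 regions, 6221 had a peak in 1 library only, 2035 of them in BE IP replicate 1 and 401 in NC IP replicate 1. Within the m6A machinery, Zc3h13, a writer subunit, carried 14 or 15 peaks in BE and 9 to 12 in NC libraries, and Wtap 6 or 7 in BE and 7 or 8 in NC, in lists of different length.

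Hepatocyte genes stood high in BE replicate 1 alone. A swap with an NC sample is argued against: its striated muscle score lay 4.07 below the NC mean (difference -4.07, log2) and 0.0942 below the mean of the other BE libraries (difference -0.0942). RNA or cells from liver, carried over in dissection or handling, are a candidate explanation: 100% of 19 hepatocyte genes not seen beforehand were over 2-fold above every other library, and 15 of 31 hepatocyte genes carried a peak in BE IP replicate 1 against at most 2 elsewhere; no sort removed such cells. Columnar epithelium remains open, since Krt18 and Krt8, high in that library, are also made by liver and many members were not analysed here. Against it, Krt19 stood at 1.79 CPM there and 4.53 CPM in NC replicate 1. The biliary and ductal genes stood at a median of 0.760 times the highest other library, with 2 of 11 over 2-fold. That list cannot decide the question, since some members were abundant in every library. Epcam ran from 72.3 to 171 CPM and Aqp1 from 83.9 to 107 CPM. Onecut1 and Onecut2, the members over 2-fold, stood at only 1.21 and 2.32 CPM in BE replicate 1. Among the 31 hepatocyte genes are members of the intestinal list such as Apob and Apoa1, and whether either source brings the interferon genes (25 of 25 over 2-fold) was not tested.

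Cell cycle and inflammatory lists stood higher, and muscle lists lower, in BE. If a lower share of muscle wall raised all other cell types alike, their scores would keep their distances. The cell cycle score rose 2.10 (SE 0.196) and the inflammatory score 2.71 (SE 0.314) more than the endothelial score on the log2 scale. They rose 0.93 (SE 0.148) and 1.54 (SE 0.342) more than the squamous score. Yet the endothelial score itself moved apart from the squamous score (difference -1.17, SE 0.164), so these references did not move alike. Both lists rose more than both references. This argues against a lower share of muscle wall that raised other cell types alike as the whole cause of those rises. As a cause of part of them it is not excluded, and a lower share that raised cell types unevenly was not tested. Scaling by a few abundant NC genes is argued against: without 35 genes, the 20 most abundant of each library, and with scaling by the remaining counts, the median of all genes moved by -0.20 from scaling by all counts, while the list medians were 2.06 and 2.64 (lower quartiles 1.69 and 1.60). Liver RNA is argued against by both lists passing without BE replicate 1 (the higher adjusted p was 1.0e-07; over all fits but that with an estimated correlation, where both lists gave 0.179, the inflammatory list ran from 1.8e-11 to 8.4e-04). A response of the tissue to reflux or to the operation itself remains open as a hypothesis. These cannot be told apart, since the BE rats were operated on and the NC rats were untreated. A different mix of epithelium and infiltrating cells, and whether the muscle lists fell through less muscle or lower expression within it, were not tested.

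Genes with group-specific m6A may reflect abundance or list length. Among genes changed less than 1.2-fold, 46 were group-specific, against at most 17 in the other splits, and with lists of equal length 34 against at most 13. The excess thus remained where the estimated change was small. Such estimates carry error, with an SE of 0.639 around -0.10 on the log2 scale for Cyp2c79, so abundance is not excluded. The other splits mix BE and NC libraries, so the excess does not tell abundance from other differences between the groups. Longer BE lists remain a candidate explanation for the balance between BE-only and NC-only genes, whose ratio was 1.09 with full lists, 0.520 with equal lists and 0.898 with a fold enrichment of at least 4. IP depth and antibody efficiency per library were not tested. A difference in methylation of such transcripts stays a hypothesis.

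The 6 libraries of a kind allow 10 splits, too few for a share under 0.05. Every other split also has BE and NC libraries on both sides. Their difference then enters the spread within each side, which lowers the number of single genes called. Part of it stays between the sides, where tests of lists and sets can still pass. The other splits are thus not free of the difference, and no conclusion on chance is drawn from them. The real split gave 5995 genes, and 3384 at 2-fold, against 0 and 0 for the highest other split (edgeR; 1 split of 10 as large in each case). It gave 2017 group-specific regions against 232, 488 genes against 61, and 3 fixed lists over-represented against 0 (1 split of 10 as large in each case). For list tests, 6 passed in the real split and up to 9 in another, and 8 of the 10 splits gave as many; for the sets of genes with group-specific m6A, 2 passed in the real split and in 10 of 10 splits.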
